A study of Arabidopsis thaliana with 12 samples.

How the data were processed

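RNA was sequenced from whole roots of Arabidopsis thaliana Columbia seedlings in 12 libraries, 2 per group in 6 groups. Seedlings were treated 4 days after planting with 2 uL of bacterial inoculum at an OD595 of 1 or with 2 uL of 0.9% saline, and at least 50 root systems were pooled per biological replicate, per the labels. The groups were saline, Azospirillum brasilense Az39 and its ipdc mutant, each at 24 h and at 7 d after treatment, under 16 h of light and 8 h of dark. Reads were 150 bp, single-end. The library kit named in the labels is a DNA library kit that does not mark strand.

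The deposited values were raw counts of reads per gene, made by the authors with HISAT2 2.2.1 and featureCounts against TAIR10, per the submitters' processing notes. Settings for strand, reads that match several places and the feature counted are not given in the sources used here, so counts of close paralogs, overlapping genes and antisense transcripts were uncertain. The table held 21200 genes, of which 469 had no count in any library. Of their identifiers, 21120 matched a locus in the TAIR10.1 annotation, which was used for gene names only, and no positions are given. It held 4 mitochondrial genes and 0 chloroplast genes, and 6327 of the 27444 nuclear protein-coding genes of the annotation were not in it and were not analysed here.

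Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 6 groups (minimum count 10, minimum total 15, proportion 0.7), which left 18867 genes. Libraries were scaled by TMM. A single model with a mean for each of the 6 groups was fitted to all 12 libraries, which left 6 residual degrees of freedom, and contrasts were tested with the two-sided edgeR quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are on the log2 scale with a prior count of 0.125, and the error after each ± is a standard error, the absolute log2 fold change divided by the square root of F, with n = 2 libraries per group throughout. The biological coefficient of variation was 24.5%. That error was left undefined for a few genes with a change of 0, where F was not positive.

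In all, 25 gene lists were fixed before the data were examined, as were the comparisons, tests, the rule for naming genes and all alternatives other than those said to have been added. Of their 530 entries, 506 were in the table and 493 were tested, and 18 had an identifier that the annotation names differently or not at all. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values, with Benjamini-Hochberg adjustment over 150 tests (25 lists by 6 treatment comparisons), and again with a correlation estimated per list and with fry. Of the 150 tests, 54 passed with the preset correlation, 0 after adjustment with an estimated correlation, and 1 with fry, so each list result is given with its unadjusted p under the estimated correlation. Medians of lists are of log2 fold changes unless given as folds. In addition, 4 lists were added after the data were seen. The comparisons between times and the added lists were each adjusted as a set of their own. With an estimated correlation 0 of either set passed (smallest adjusted p = 0.471 between times and 0.895 for the added lists). With fry 3 passed between times and 0 of the added lists (smallest adjusted p = 0.534).

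Genes were named by rule. Each treatment comparison drew on the 8 highest and 8 lowest called fold changes. These needed a mean log2 CPM of at least 1 and no overlap between the libraries of the groups compared. Up to 4 called members per list with the smallest adjusted p were added. A further 12 genes of auxin response, defence and nutrient uptake were picked whatever their result. Not all of the 12 are reported in every comparison. With fewer than 5 calls, the 3 highest and 3 lowest of the 10 smallest p were named. For the saline groups the 5 highest and 5 lowest were named, and for differences between times the 5 smallest p. Other genes are said to have been chosen after their values were seen. Genes with 1 to 3 counts in a compared group are not named with a fold change.

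Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, other low-count filters, fits to fewer libraries, the replicate mark as a block, leaving out each library in turn (the remaining library of the group was assumed to vary like the other groups), a test against a 1.5-fold change, and leaving out organelle genes. Added after the data were seen were a fit without both ipdc 24 h libraries and fits with each library's share of photosynthesis or seed storage transcripts as covariates. RLE moved the median log2 fold change of all genes by less than 0.1 in each comparison. Also added were simulations with a response to Az39 alone. Responses to the 2 strains share their saline libraries, so their overlap was set beside 20 simulations without treatment effects. The saline libraries (2 per time) could not be split into separate controls for each strain.

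The procedure was tested on simulated data with 100 genes changed at each of 2 sizes. At a 4-fold change it called between 74% and 87% of them, and at a 2-fold change between 9% and 15%. Between 4 and 7 calls per comparison fell on genes that had not been changed, out of 91 to 108 calls. Simulated counts were drawn gene by gene with the fitted dispersions. They held no shifts of many genes together and no seed or shoot transcripts that differ between replicates. Rates in the real comparisons were not measured. Depth was 9665704 to 21541793 counts per library. Shares of counts carry counting error only, which at this depth is small beside the spread between replicates.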

Results

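The series asked how roots respond to Azospirillum brasilense Az39, a soil bacterium that promotes plant growth, and how much of the response involves auxin. Its ipdc mutant lacks indole-3-pyruvate decarboxylase, an enzyme of bacterial auxin (indole-3-acetic acid) synthesis. Whole roots were sampled 24 h and 7 d after inoculation or after saline alone, with n = 2 libraries in each of 6 groups. Counts in the 24 h libraries totalled 18649442 and 21541793 with saline, 9665704 and 14289186 with Az39, and 11807598 and 12010058 with ipdc. The 7 d totals were 18773891 and 19330423 with saline, 17212991 and 16708899 with Az39, and 15424136 and 14141640 with ipdc. The beta-glucosidase gene PYK10, a marker of root endoplasmic reticulum bodies, was the most abundant gene in 11 libraries, at 0.524% to 1.18% of counts. In the first ipdc 24 h replicate the seed storage protein gene CRA1 took that place with 2.91% of counts.

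Seed storage transcripts made up 5.11% and 0.296% of counts in the ipdc 24 h replicates and between 0.0015% and 0.128% in the other 10 libraries. Photosynthesis transcripts made up 0.398% and 2.32% in the ipdc 24 h replicates and between 0.0664% and 0.344% elsewhere. Across genes, which are not independent replicates, the Spearman rho between replicates was lowest in ipdc 24 h, at 0.924, and highest in ipdc 7 d, at 0.982. The first principal component held 43.2% of the variance and the second 21.0%, and the ipdc 24 h libraries lay at -76.2 and -43.6 on the second.

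**Figure D1:**
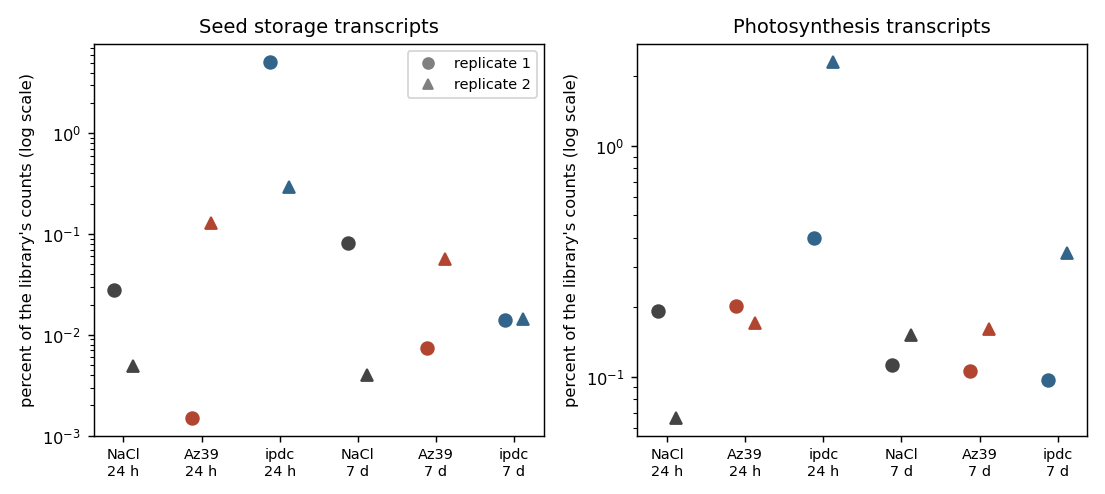
Percent of each library's counts in seed storage genes (left) and in photosynthesis genes (right), on log axes, for the 6 groups with each replicate as a point. The highest seed storage share was 5.11%, in ipdc 24 h replicate 1, and the highest photosynthesis share 2.32%, in ipdc 24 h replicate 2.

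**Figure D2:**
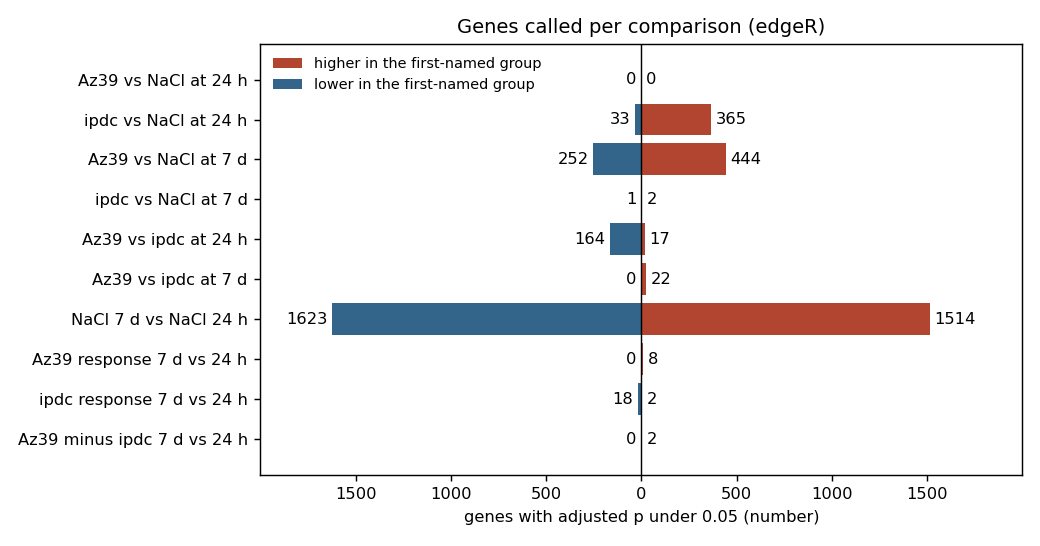
Number of genes called by edgeR in each comparison at an adjusted p under 0.05, higher in the group named first to the right and lower to the left. Az39 gave 0 calls at 24 h and 696 at 7 d, and ipdc 398 at 24 h and 3 at 7 d.

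Az39 against saline at 24 h, the early response to the wild-type strain, gave 0 genes past the threshold by edgeR. The highest fold change among the 10 smallest p belonged to the lipid transfer protein gene LTP4 (AT5G59310), at 6.32 ± 1.04. Next were AT1G52100, at 2.52 ± 0.46, and AT4G00780, at 2.49 ± 0.62. The expansin-like gene EXLB1 (AT4G17030) stood at 0.89 ± 0.21 and AT2G01610 at -1.30 ± 0.32. Auxin response genes did not pass either. The Aux/IAA repressor genes IAA5 (AT1G15580) and IAA19 (AT3G15540) stood at 1.68 ± 0.79 and 0.38 ± 0.22. The auxin-conjugating enzyme gene GH3.3 (AT2G23170) stood at 0.53 ± 0.61, and LBD16 (AT2G42430), a regulator of lateral root initiation, at 0.24 ± 0.38. The camalexin pathway cytochrome P450 gene CYP71A12 (AT2G30750) stood at 2.17 ± 1.02 and the defence receptor kinase gene FRK1 (AT2G19190) at -1.69 ± 0.75. Each of these 2 rested on 1 library, with CYP71A12 at -0.72 without the first Az39 replicate and FRK1 at 0.30 without the second saline replicate. GH3.3 stood at -0.20 without the first Az39 replicate and LBD16 at -0.34 without the second.

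Several lists shifted slightly as groups although 0 of their members passed, over all genes or adjusted over the list alone. All 10 tested genes of xylem secondary walls were above 0 (median 0.46, camera adjusted p = 5.4e-06, p = 0.0720 with an estimated correlation). So were 24 of the 27 cell cycle genes (median 0.17, camera adjusted p = 6.3e-05, p = 0.29 with an estimated correlation). Of 27 photosynthesis genes, markers of another tissue, 24 were above 0 (median 0.60, camera adjusted p = 8.7e-07, p = 0.273 with an estimated correlation). The 13 hypoxia genes stood higher as a group (median 0.35, camera adjusted p = 9.8e-04, p = 0.0734 with an estimated correlation). The 19 salicylic acid genes stood lower (median -0.39, camera adjusted p = 0.0053, p = 0.2 with an estimated correlation). So did pattern-triggered immunity (median -0.16, camera adjusted p = 0.0225, p = 0.3985 with an estimated correlation) and nitrogen genes (median -0.19, camera adjusted p = 0.0225, p = 0.361 with an estimated correlation). Suberin genes (median -0.25, camera adjusted p = 0.0197, p = 0.475 with an estimated correlation) and aquaporins (median -0.08, camera adjusted p = 0.0203, p = 0.284 with an estimated correlation) were also lower. These calls rested on single libraries. The xylem call was lost without the first Az39 replicate (median 0.02) and the cell cycle call without the second saline replicate (median -0.03). The photosynthesis call was also lost without the second saline replicate (0.0930), and its median was 1.31 without the first and 0.38 without the first Az39 replicate. The hypoxia call was lost without the first saline replicate (0.22) or the second Az39 replicate (0.02). The salicylic acid call was lost without the second saline replicate (-0.13) or the second Az39 replicate (-0.35). The medians were 0.37 (cell cycle) and -0.66 (salicylic acid) without the first saline replicate, 0.53 (hypoxia) without the second, 0.65 (hypoxia) without the first Az39 replicate and 0.73 (xylem) without the second. In all, 9 of the 25 lists passed, and 9 were lost without at least 1 of the 4 libraries. With edgeR 0 genes were called and 249 had an unadjusted p under 0.05. DESeq2 called 2, LTP4 and AT1G52100, and limma-voom 0.

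Among the highest changes of the ipdc strain against saline at 24 h were the metallothionein gene AtMT4b (AT2G23240), active in seeds, at 9.05 ± 1.86, adjusted p = 0.0435, and the late embryogenesis abundant protein gene ATECP31 (AT3G22500), at 8.64 ± 1.78, adjusted p = 0.0437. Others were AT1G03106, at 8.69 ± 1.71, adjusted p = 0.0397, and AT4G25580, at 8.33 ± 1.76, adjusted p = 0.0458. The abscisic acid regulator of seeds ABI5 (AT2G36270) rose by 4.75 ± 0.99, adjusted p = 0.0446. Without the first ipdc replicate, which held 5.11% seed storage transcripts, ATECP31 stood at 5.21, AT4G25580 at 4.89 and ABI5 at 2.22. Small heat shock protein genes rose as well. HSP17.6A (AT5G12030) stood at 8.42 ± 1.53, adjusted p = 0.0350, HSP23.6-MITO (AT4G25200) at 6.88 ± 1.19 and HSP17.4 (AT3G46230) at 6.34 ± 1.09, adjusted p = 0.0287. They were highest in the first replicate, with HSP17.6A at 477 and 45.3 CPM in the ipdc replicates, HSP17.4 at 134 and 20.2 and HSP23.6-MITO at 21.5 and 3.01.

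Photosynthesis genes stood higher throughout their list. Of 27 tested members, 4 rose over all genes and 26 adjusted over the list alone (median 3.49, camera adjusted p = 5.8e-20, p = 0.0742 with an estimated correlation). They included the Rubisco activase gene RCA (AT2G39730), at 3.52 ± 0.76, adjusted p = 0.0483, and the Calvin cycle gene GAPB (AT1G42970), at 3.24 ± 0.64. The antenna protein genes LHCB6 (AT1G15820) and LHCA4 (AT3G47470) stood at 3.41 ± 0.73 and 2.59 ± 0.54. Without the second ipdc replicate, which held 2.32% photosynthesis transcripts, the list median was 1.83, and RCA stood at 2.12, GAPB at 2.13, LHCB6 at 1.89 and LHCA4 at 1.25. In the heat shock list 3 of 11 genes rose over all genes and 8 adjusted over the list alone (median 2.38, camera adjusted p = 6.3e-05, p = 0.0672 with an estimated correlation). The sugar-repressed asparagine synthetase gene ASN1 (AT3G47340) rose 8.00-fold (adjusted p = 0.0350), and its log2 fold change was 2.00 without the first ipdc replicate. Seed storage genes, a list added after the data were seen, had 1 of 14 members higher over all genes and 9 adjusted over the list alone (median 5.72, camera adjusted p = 2.0e-04, p = 0.252 with an estimated correlation). Their share was 5.11% of counts in the first ipdc replicate.

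With ipdc at 24 h 33 genes were lower than with saline. The gibberellin-regulated gene GASA5 (AT3G02885) stood at -2.27 ± 0.39, adjusted p = 0.0284, and the extensin-like receptor kinase gene PERK4 (AT2G18470) at -2.72 ± 0.50, adjusted p = 0.0364. The auxin-conjugating gene GH3.17 (AT1G28130) stood at -1.20 ± 0.23, adjusted p = 0.0380. The receptor kinase gene HAE (AT4G28490), which acts in organ separation and lateral root emergence, stood at -1.32 ± 0.26. HAE lost its call without any 1 of the 4 libraries compared, at -1.59 to -1.01. Also lower were AT4G14060, at -2.06 ± 0.23, adjusted p = 0.0102, AT2G01610, at -2.16 ± 0.34, and FLS2 (AT5G63580), a flavonol synthase family member and not the flagellin receptor, at -2.14 ± 0.43. Of 27 cell cycle genes 1 was above 0 and 0 passed (median -0.44, camera adjusted p = 1.8e-07, p = 0.188 with an estimated correlation). Cytokinin genes had 0 of 22 called, or 1 lower adjusted over the list alone (median -0.56, camera adjusted p = 7.3e-05, p = 0.0863 with an estimated correlation). Among 30 auxin response genes 1 fell over all genes, and 1 rose and 1 fell adjusted over the list alone (median -0.26, camera adjusted p = 0.0260, p = 0.0955 with an estimated correlation). That list call was lost without the second saline replicate (median -0.12) or the first ipdc replicate (-0.10), and its median was -0.39 without the second. The cytokinin median was -0.33 without the second saline replicate. The cell cycle median was -0.25 without the first ipdc replicate and -0.78 without the second. The auxin-induced genes GH3.3 and IAA19 did not pass, at 0.35 ± 0.61 and -0.20 ± 0.22. The sign for GH3.3 rested on the second ipdc replicate, with 22 and 88 counts with ipdc and 73 and 90 in the larger saline libraries.

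In this comparison edgeR called 398 genes, 365 higher and 33 lower, at an adjusted p under 0.05. The count was 6 without the first saline replicate, 0 without the second, 678 without the first ipdc replicate and 1318 without the second. It was 0 in fits to the libraries of that time or those groups alone, 3 with the seed storage share as a covariate (1 higher, 2 lower), 0 with both shares, 37 with a replicate block within each time, 14 against a 1.5-fold change and 1399 with DESeq2.

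Az39 against ipdc at 24 h was the direct test of the strains at the early time. Heat shock genes were lower with Az39 in 3 of 11 cases, or 7 adjusted over the list alone (median -2.35, camera adjusted p = 3.7e-04, p = 0.0927 with an estimated correlation). HSP17.6A stood at -9.16 ± 1.67, adjusted p = 0.0440 and HSP17.4 at -5.84 ± 1.08, adjusted p = 0.0459, or -3.87 without the first ipdc replicate. Photosynthesis genes had 0 of 27 members past the threshold over all genes and 23 lower adjusted over the list alone (median -2.92, camera adjusted p = 2.6e-13, p = 0.13 with an estimated correlation). The second ipdc replicate held a 2.32% share of these transcripts, and the median was -1.14 without it. The sugar-repressed gene ASN1, 9.82-fold lower (adjusted p = 0.0387), and the dormancy-associated gene DRM2 (AT2G33830), at -1.77 ± 0.33, adjusted p = 0.0459, were lower with Az39. Also lower was the methionine-derived glucosinolate gene CYP79F1 (AT1G16410), at -5.81 ± 0.94, adjusted p = 0.0313, with 6 counts in the Az39 libraries. Higher with Az39 were the transporter gene ABCG39 (AT1G66950), at 2.65 ± 0.44, adjusted p = 0.0365, and AT1G03820, at 1.55 ± 0.22, adjusted p = 0.0228. AT4G14060 stood at 1.92 ± 0.23 and AT1G33440 at 1.40 ± 0.21.

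Growth-related lists stood higher with Az39 than with ipdc at 24 h, with 0 members called over all genes. The gap lay mostly on the ipdc side. Against saline the medians with ipdc were -0.44 (cell cycle), -0.26 (auxin response), -0.26 (lateral root) and -0.56 (cytokinin). With Az39 they were 0.17, 0.08, 0.12 and -0.03. Between the strains all 27 cell cycle genes were above 0, 3 of them called adjusted over the list alone (median 0.64, camera adjusted p = 2.8e-12, p = 0.0992 with an estimated correlation). The 30 auxin response genes had 2 higher and 1 lower adjusted over the list alone (median 0.40, camera adjusted p = 0.0015, p = 0.0349 with an estimated correlation). The 18 lateral root genes had 0 (median 0.38, camera adjusted p = 0.0177, p = 0.0231 with an estimated correlation, fry adjusted p = 0.0299). Cytokinin genes also stood higher (median 0.55, camera adjusted p = 5.7e-05, p = 0.0783 with an estimated correlation). Without the first ipdc replicate, which held 5.11% seed storage transcripts, the auxin response and lateral root calls were lost (medians 0.27 and 0.24) and the cell cycle median was 0.40. The lateral root call was also lost without the second ipdc replicate (median 0.58), and the auxin response median was then 0.68. By edgeR 181 genes differed, 17 higher and 164 lower with Az39. The count was 0 without either Az39 replicate, 598 without the first ipdc replicate and 1356 without the second, 0 in fits to fewer libraries, 4 with the seed storage share as a covariate and 2 with both shares (each of these higher with Az39), 603 with the photosynthesis share, 6 with a replicate block within each time, 8 against a 1.5-fold change, 74 with limma-voom and 1394 with DESeq2.

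After 7 d Az39 roots carried more transcripts of jasmonate synthesis and signalling than saline roots. The repressor gene JAZ10 (AT5G13220), a marker of jasmonate response, rose by 5.87 ± 0.64, adjusted p = 0.0054, and the synthesis gene AOC1 (AT3G25760) by 5.70 ± 0.87, adjusted p = 0.0132. The jasmonate-responsive aminotransferase gene TAT3 (AT2G24850) rose by 6.23 ± 0.73, adjusted p = 0.0065. Of 26 jasmonate genes, 10 rose and 0 fell over all genes, and 19 rose and 1 fell adjusted over the list alone (median 2.54, camera adjusted p = 1.0e-10, p = 0.0576 with an estimated correlation). They included JAZ9 (AT1G70700), at 3.51 ± 0.41, JAZ2 (AT1G74950), at 3.06 ± 0.44, and the synthesis gene OPR3 (AT2G06050), at 3.04 ± 0.41. Among the largest changes were also AT4G37710, at 6.39 ± 0.57, adjusted p = 0.0016, and the methyltransferase gene FAMT (AT3G44860), at 5.36 ± 0.88. The transcription factor gene BHLH92 (AT5G43650) stood at 5.35 ± 0.86, and AT3G22275 at 5.26 ± 0.75.

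**Figure D3:**
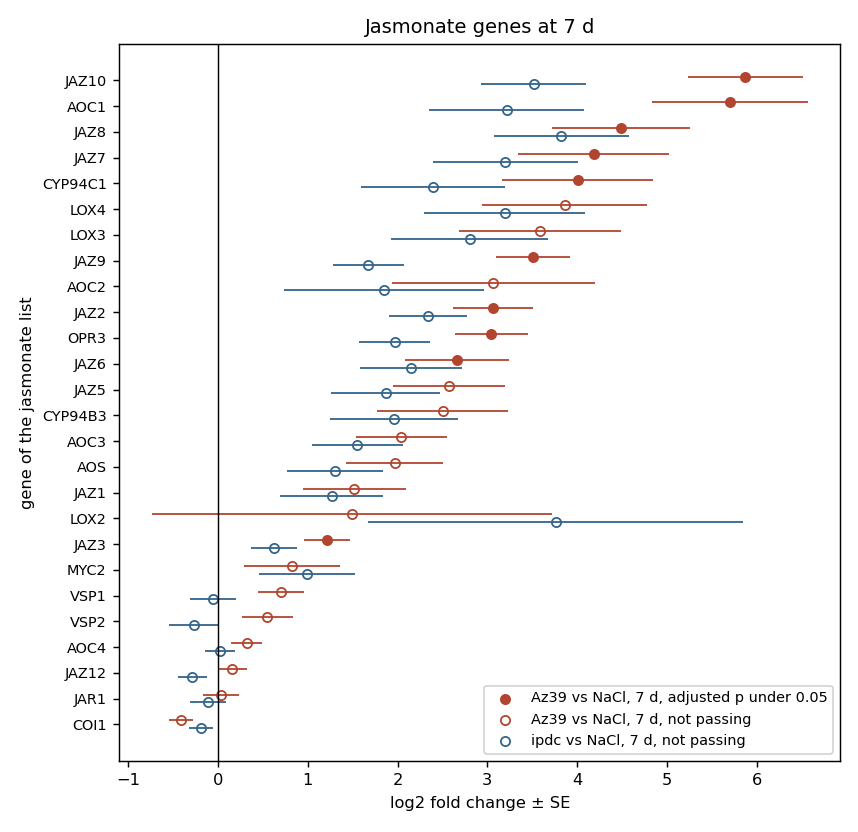
Log2 fold change against saline at 7 d (points) with the standard error (bars) for each of the 26 tested jasmonate genes, for Az39 and ipdc. Filled points passed an adjusted p under 0.05, which 10 genes did for Az39 and 0 for ipdc.

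Individual genes of salicylic acid signalling, auxin response and tryptophan synthesis rose beside them. In the salicylic acid list 2 of 19 genes rose over all genes and 8 adjusted over the list alone (median 0.76, camera adjusted p = 0.0016, p = 0.159 with an estimated correlation). The called members were the salicylic acid exporter gene EDS5 (AT4G39030), at 1.97 ± 0.25, adjusted p = 0.0087, and the transcription factor gene WRKY38 (AT5G22570), at 4.66 ± 0.59, adjusted p = 0.0081. Among 32 genes of pattern-triggered immunity 2 rose and 2 fell over all genes, or 6 and 3 adjusted over the list alone (median 0.05, camera adjusted p = 0.544). WRKY18 (AT4G31800) stood at 3.66 ± 0.50, WRKY11 (AT4G31550) at -1.34 ± 0.22, and the elicitor peptide precursor gene PROPEP1 (AT5G64900) was 2.84-fold higher (log2 0.98 without the second Az39 replicate). Auxin response genes numbered 2 higher of 30 over all genes and 3 adjusted over the list alone (median 0.41, camera adjusted p = 0.0545, p = 0.129 with an estimated correlation). The list as a whole did not pass. The called members were the Aux/IAA genes IAA2 (AT3G23030), at 1.62 ± 0.20, adjusted p = 0.0081, and IAA19, at 1.11 ± 0.21, adjusted p = 0.0276. IAA19 lost its call without any 1 of the 4 libraries compared, at 0.90 to 1.25. Not passing, IAA5 stood at 2.75 ± 0.73, adjusted p = 0.0650 and GH3.3 at 1.90 ± 0.59, adjusted p = 0.0933. Also not passing, and given as raw counts, GH3.5 (AT4G27260) had 635 and 494 with Az39 and 910 and 882 with saline. LBD16 had 167 and 84 against 183 and 182, and LBD29 (AT3G58190) had 38 and 91 against 39 and 60. The defence genes CYP71A12 and FRK1 had 1094 and 415 against 1550 and 1039, and 33 and 20 against 43 and 42. The anthranilate synthase genes ASA1 (AT5G05730) and ASB1 (AT1G25220), of tryptophan synthesis, rose by 1.87 ± 0.28 and 1.91 ± 0.22. The hypoxia-responsive factor gene HRE2 (AT2G47520) rose by 4.83 ± 0.62, the hemoglobin gene HB1 (AT2G16060) by 1.59 ± 0.32 and the flavonol regulator gene MYB12 (AT2G47460) by 1.43 ± 0.23.

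Uptake of iron, nitrogen and water was represented among the genes that fell with Az39 at 7 d. The iron deficiency regulator FRU (AT2G28160), also known as FIT, stood at -1.43 ± 0.20, adjusted p = 0.0110, the iron transporter gene IRT1 (AT4G19690) at -1.65 ± 0.37, adjusted p = 0.0432, and the ferric reductase gene FRO2 (AT1G01580) at -1.84 ± 0.42. In that list 4 of 23 genes fell over all genes and 4 adjusted over the list alone (median -0.55, camera adjusted p = 0.0094, p = 0.0503 with an estimated correlation). The ammonium transporter genes AMT1;1 (AT4G13510) and AMT1;3 (AT3G24300) stood at -1.46 ± 0.28 and -1.78 ± 0.36, and the nitrate regulator gene NLP7 (AT4G24020) at -1.16 ± 0.22. In the nitrogen list 4 of 22 fell over all genes, and 8 fell and 1 rose adjusted over the list alone (median -0.50, camera adjusted p = 4.9e-04, p = 0.194 with an estimated correlation). The nitrate transporter gene NRT2.1 (AT1G08090) did not pass, at -1.65 ± 0.75, adjusted p = 0.21. Of 19 aquaporin genes 5 fell over all genes and 10 adjusted over the list alone (median -0.57, camera adjusted p = 2.4e-04, p = 0.122 with an estimated correlation). Among them were TIP2;2 (AT4G17340), at -1.22 ± 0.25, TIP2;3 (AT5G47450), at -1.44 ± 0.33, and PIP2;4 (AT5G60660), at -1.24 ± 0.28. The calls of IRT1, FRO2, AMT1;1, NLP7 and PIP2;4 were lost without any 1 of the 4 libraries compared. Their signs held, with IRT1 at -1.79 to -1.61 and FRO2 at -2.02 to -1.74.

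Cytokinin genes fell in 4 of 22 cases over all genes and 7 adjusted over the list alone (median -0.62, camera adjusted p = 8.7e-05, p = 0.0880 with an estimated correlation). The synthesis genes IPT5 (AT5G19040) and CYP735A2 (AT1G67110) stood at -2.18 ± 0.44 and -1.49 ± 0.31, and the receptor gene AHK4 (AT2G01830) at -0.64 ± 0.15. The dark-inducible gene SEN1 (AT4G35770) stood at -2.69 ± 0.59. It was the 1 of 6 sugar starvation genes that fell over all genes, and 3 fell adjusted over the list alone (median -1.07, camera adjusted p = 0.0031, p = 0.0321 with an estimated correlation). The auxin- and age-regulated gene SAUR36 (AT2G45210) stood at -2.30 ± 0.33 and AT5G48430 at -2.76 ± 0.40. The phosphate exporter gene PHO1 (AT3G23430) stood at -1.14 ± 0.23 and the abscisic acid phosphatase gene ABI1 (AT4G26080) at -1.08 ± 0.21. IPT5, AHK4, SEN1, PHO1 and ABI1 lost their calls without any 1 of the 4 libraries compared, and kept their signs. Cell cycle genes had 0 of 27 called (median 0.44, camera adjusted p = 0.0064, p = 0.446 with an estimated correlation). That list call was lost without the first Az39 replicate (median 0.03), while the median was 0.70 without the second.

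By edgeR 696 genes passed, 444 higher and 252 lower. The split turned to 356 higher and 423 lower in the fit to the libraries of that time and was 610 and 589 without both ipdc 24 h libraries. Without the second saline replicate 4 passed, without the first 218, without the first Az39 replicate 227, and the salicylic acid median was 1.26 without the first saline replicate and 0.51 without the second. Other counts were 69 with those 4 libraries alone, 326 with a replicate block within each time, 85 against a 1.5-fold change, 437 with both shares as covariates, 1085 with limma-voom and 1981 with DESeq2.

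The ipdc strain against saline at 7 d gave 3 called genes. The aluminium-activated malate transporter gene ALMT1 (AT1G08430) rose by 2.55 ± 0.29, adjusted p = 0.0385, and the elicitor peptide precursor gene PROPEP4 (AT5G09980) rose by 1.90 ± 0.18, adjusted p = 0.0229. AT2G16005 stood lower, at -2.13 ± 0.23, adjusted p = 0.0385, and lost its call without any 1 of the 4 libraries compared. Next in line and not passing were the arabinogalactan protein gene FLA13 (AT5G44130), at -2.34 ± 0.29, adjusted p = 0.0527, and AT4G28085, at 1.94 ± 0.29, adjusted p = 0.122. GH3.3 and IAA19 did not pass, at 1.31 ± 0.58, adjusted p = 0.475 and 0.60 ± 0.21, adjusted p = 0.371, nor did IRT1, at -0.76 ± 0.36, or NRT2.1, at -2.58 ± 0.80. The ipdc replicates differed for IRT1, with 339 and 798 counts, against 1175 and 1408 with saline.

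Several lists shifted as groups, with 0 members called over all genes. Jasmonate genes had 14 of 26 higher adjusted over the list alone (median 1.86, camera adjusted p = 2.7e-09, p = 0.0760 with an estimated correlation). JAZ10 stood at 3.51 ± 0.58 and OPR3 at 1.97 ± 0.39. Salicylic acid genes had 1 of 19 higher adjusted over the list alone (median 0.95, camera adjusted p = 6.2e-06, p = 0.0681 with an estimated correlation). Genes of pattern-triggered immunity had 6 of 32 higher adjusted over the list alone (median 0.58, camera adjusted p = 4.0e-04, p = 0.221 with an estimated correlation). That call was lost without the second saline replicate (median 0.09), and the median was 1.22 without the first. Xylem secondary wall genes had 8 of 10 lower adjusted over the list alone (median -0.76, camera adjusted p = 1.6e-08, p = 0.0373 with an estimated correlation). The cellulose synthase genes CESA4 (AT5G44030) and IRX3 (AT5G17420) stood at -0.86 ± 0.19 and -0.72 ± 0.17. Cytokinin genes had 5 of 22 lower adjusted over the list alone (median -0.51, camera adjusted p = 4.8e-07, p = 0.0426 with an estimated correlation), and aquaporin genes 8 of 19 (median -0.57, camera adjusted p = 1.3e-05, p = 0.0832 with an estimated correlation). Iron deficiency genes also stood lower (median -0.22, camera adjusted p = 0.0191, p = 0.0678 with an estimated correlation). So did nitrogen (median -0.22, camera adjusted p = 5.1e-04, p = 0.194 with an estimated correlation) and phosphate starvation genes (median -0.26, camera adjusted p = 0.0057, p = 0.0355 with an estimated correlation). Sugar starvation genes were lower too (median -0.71, camera adjusted p = 0.0015, p = 0.0285 with an estimated correlation). Root hair genes stood higher (median 0.39, camera adjusted p = 0.0103, p = 0.356 with an estimated correlation). Cell cycle genes did as well (median 0.32, camera adjusted p = 0.0149, p = 0.486 with an estimated correlation). In all, 12 of the 25 lists passed, and 3 were lost without at least 1 of the 4 libraries. Salicylic acid kept its call without each library, with a median of 0.63 without the first ipdc replicate.

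Of the 3 genes that passed in edgeR, 2 were higher (66.7%) and 1 lower, and with RLE scaling 2 were higher (50.0%) and 2 lower, and 1980 genes had an unadjusted p under 0.05. The count was 8 without the first saline replicate, 0 without the second, 1 without the first ipdc replicate and 0 without the second. It was 0 with fewer libraries in the fit, with a replicate block within each time, with either share as a covariate or against a 1.5-fold change, 5 without a low-count filter, 6 with a replicate block (2 higher, 4 lower) and 379 with DESeq2 (175 higher, 204 lower).

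Az39 against ipdc at 7 d, the direct test of what the mutation changed at the late time, gave 22 genes, each higher with Az39. The glutathione S-transferase genes GSTU5 (AT2G29450) and GSTU6 (AT2G29440), of detoxification, were 9.82-fold (adjusted p = 0.0048) and 7.40-fold higher (adjusted p = 0.0043). The ethylene response factor gene ABR1 (AT5G64750) stood at 3.11 ± 0.41, adjusted p = 0.0314 and AT4G25433 at 4.12 ± 0.44, adjusted p = 0.0185. The Aux/IAA gene IAA2 was higher by 1.57 ± 0.20, adjusted p = 0.0314 and the dehydrin gene LTI30 (AT3G50970) by 1.38 ± 0.20, adjusted p = 0.0486. AT4G25433 and LTI30 lost their calls without any 1 of the 4 libraries compared. Other members of the 22, chosen after their values were seen, were the Aux/IAA gene IAA18 (AT1G51950), at 1.25 ± 0.17, adjusted p = 0.0327, and the anion channel gene SLAH2 (AT4G27970), at 1.89 ± 0.23. IAA5 did not pass, at 3.33 ± 0.79, adjusted p = 0.275, and IAA19 stood at 0.52 ± 0.21.

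Of 30 auxin response genes 1 was higher with Az39 over all genes, and 3 were higher and 1 lower adjusted over the list alone (median 0.22, camera adjusted p = 0.146, p = 0.223 with an estimated correlation). As a list it did not pass. Nor did the iron deficiency (camera adjusted p = 0.0928), nitrogen (0.0839), sugar starvation (0.248) and cell cycle lists (0.243) pass between the strains. Jasmonate genes had 3 of 26 higher adjusted over the list alone and 0 over all genes (median 0.67, camera adjusted p = 3.1e-06, p = 0.136 with an estimated correlation). The median was 0.35 without the second Az39 replicate and 0.37 without the second ipdc replicate. All 12 flavonoid genes were above 0, with 2 higher adjusted over the list alone and 0 over all genes (median 0.95, camera adjusted p = 2.4e-04, p = 0.0496 with an estimated correlation). Xylem genes were above 0 in 10 of 10 cases, with 0 called (median 0.49, camera adjusted p = 7.3e-05, p = 0.102 with an estimated correlation). Hypoxia genes were above 0 in 8 of 13 cases, with 0 called over all genes (median 0.28, camera adjusted p = 0.0225, p = 0.169 with an estimated correlation). Genes of pattern-triggered immunity were above 0 in 8 of 32 cases, with 0 called (median -0.31, camera adjusted p = 0.0031, p = 0.287 with an estimated correlation). Root hair genes were above 0 in 1 of 22 cases, with 0 called (median -0.75, camera adjusted p = 5.8e-08, p = 0.0901 with an estimated correlation). The expansin gene EXPA18 (AT1G62980) stood at -1.25 ± 0.41 and the wall protein gene LRX1 (AT1G12040) at -0.76 ± 0.32, and the list median was -1.15 without the second Az39 replicate.

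With edgeR 22 genes were higher with Az39 and 0 lower, 1743 had an unadjusted p under 0.05, limma-voom called 35 and DESeq2 184. The count was 2 and 6 without the first and second Az39 replicate, 3 and 0 without the first and second ipdc replicate, 4 with a replicate block within each time, 3 against a 1.5-fold change and 5 with both shares as covariates.

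**Figure D4:**
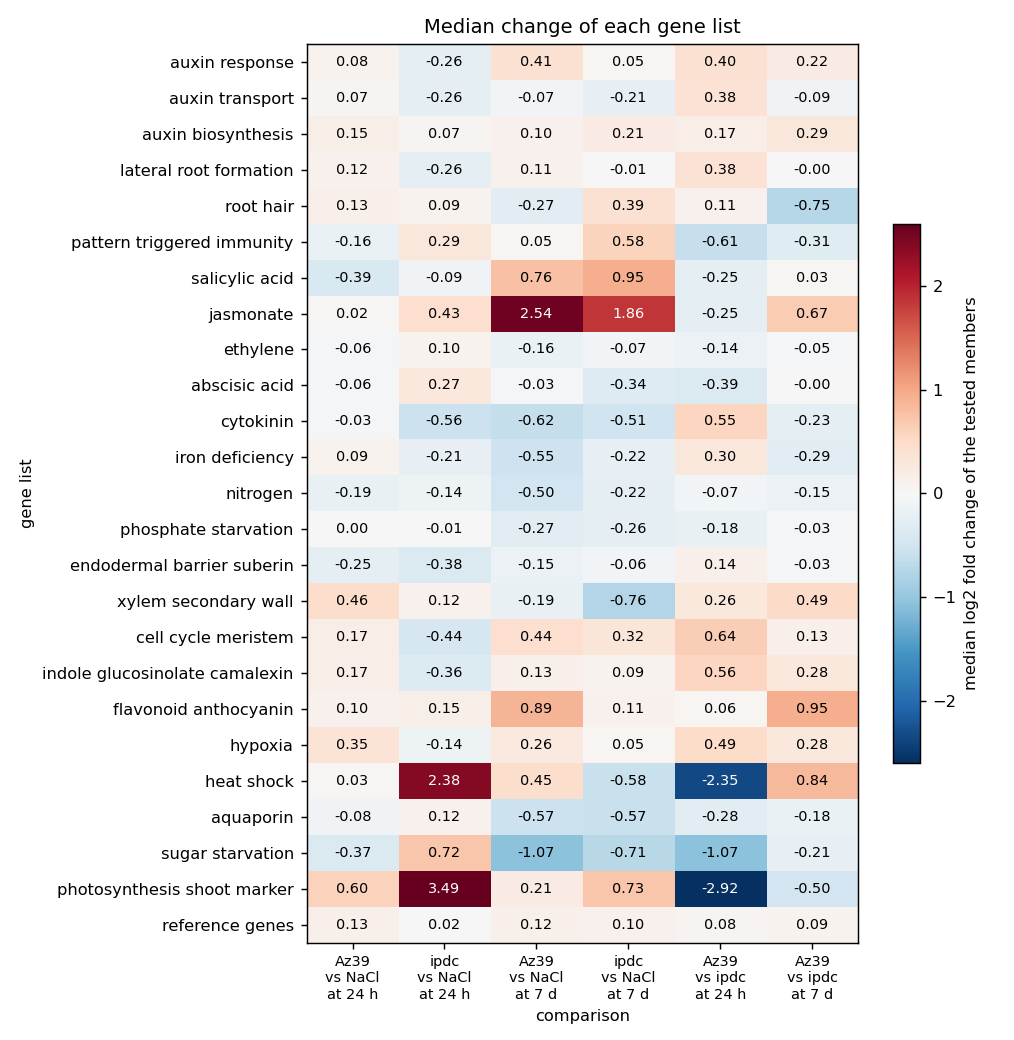
Median log2 fold change of the tested members of each of the 25 gene lists in the 6 treatment comparisons, as color and number. Photosynthesis and heat shock lists stood highest for ipdc at 24 h (3.49 and 2.38), and the jasmonate list for both strains at 7 d (2.54 and 1.86).

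Responses to both strains were compared gene by gene at each time. At 7 d 3 genes were called for both, the higher PROPEP4 and ALMT1 and the lower AT2G16005. Independent lists of those sizes would share 0.0471 higher and 0.0134 lower genes among 18867 (n1 × n2 / N). The 2 lists were not independent, as they share their saline libraries, and 20 simulations without effects shared up to 1 gene at 7 d. PROPEP4 stood at 2.62 ± 0.19 with Az39 and 1.90 ± 0.18 with ipdc, and ALMT1 at 1.85 ± 0.29 and 2.55 ± 0.29. Because the saline libraries (2 per time) were shared and could not be split, the covariance of the log2 fold changes across genes was set beside 20 simulations without effects. It was 0.322 at 7 d against a simulated 0.110 (0.0986 to 0.119), an excess of 0.212. At 24 h it was 0.167 against 0.109 (0.0953 to 0.116), an excess of 0.0573. The simulations drew each gene on its own, without shifts of many genes together in the shared saline libraries. Their range leaves out such shifts, so the excess decides nothing alone. By edgeR 0 genes were called for both at 24 h, where Az39 itself had 0 calls, and DESeq2 called 2 for both. The correlation was 0.695 at 7 d, above a simulated 0.483 (0.452 to 0.513), but 0.375 at 24 h, below all 20 simulations (mean 0.439, 0.399 to 0.470), so the 24 h measures went opposite ways. The 24 h covariance was -0.0612 without the second Az39 replicate and 0.616 without the first saline replicate, and the 7 d covariance 0.573 without the first saline replicate. The 3 shared calls became 8 without the first saline replicate, 0 without the second saline replicate or either ipdc replicate, and 277 with DESeq2.

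Saline roots changed between 24 h and 7 d, which gives the background of age and harvest. Flavonoid genes fell in 10 of 12 cases (median -1.88, camera adjusted p = 1.2e-05, p = 0.0355 with an estimated correlation). Among the lowest of all genes were the anthocyanin genes DFR (AT5G42800), at -6.19 ± 1.60, adjusted p = 0.0305, LDOX (AT4G22880), at -5.72 ± 1.48, adjusted p = 0.0307, and GSTF12 (AT5G17220), at -5.55 ± 1.11, adjusted p = 0.0156. Without the second saline 24 h replicate these stood at -3.19, -2.37 and -3.04, and DFR and LDOX lost their call without any 1 of the 4 libraries. Immune genes rose in 11 of 32 cases over all genes and 22 adjusted over the list alone (median 2.46-fold, camera adjusted p = 4.9e-07, p = 0.107 with an estimated correlation). CYP71A12 rose by 4.72 ± 1.07, adjusted p = 0.0211 and the berberine bridge enzyme-like gene AT1G26390 by 5.28 ± 0.73, adjusted p = 0.0080. Xylem genes rose in 8 of 10 cases (median 1.25, camera adjusted p = 4.3e-07, p = 0.0529 with an estimated correlation). So did aquaporin genes in 9 of 19 cases (median 0.73, camera adjusted p = 7.1e-04, p = 0.153 with an estimated correlation). Cell cycle genes fell in 10 of 27 cases, or 14 adjusted over the list alone (median -0.74, camera adjusted p = 8.1e-08, p = 0.176 with an estimated correlation). Sugar starvation genes rose in 5 of 6 cases (median 2.43, camera adjusted p = 1.4e-04, p = 0.0149 with an estimated correlation). After adjustment over the lists tested between times, 0 passed with an estimated correlation (smallest adjusted p = 0.471). With fry the flavonoid (adjusted p = 0.0378), xylem (0.0179) and sugar starvation lists (0.0179) passed, and the immunity (0.0922), aquaporin (0.0922) and cell cycle lists (0.128) did not. By edgeR 3137 genes passed, 1514 higher and 1623 lower at 7 d. The count was 27 without the first 24 h replicate, 81 without the first 7 d replicate, 1116 without the second, 299 with a replicate block within each time and 226 against a 1.5-fold change, and in each of these higher genes outnumbered lower ones.

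Whether each response itself differed between times was tested directly. The Az39 response differed for 8 genes, all with a larger value at 7 d, and the ipdc response for 20, of which 18 had the lower value at 7 d. The difference between the strains changed for 2 genes, GSTU5 and AT1G78830, a lectin family gene. GSTU5 was at 4.14 ± 0.30 with Az39 at 7 d and at -0.34 ± 0.28 at 24 h. Leaving out single libraries gave 0 to 36 genes for Az39, 0 to 826 for ipdc and 0 to 402 for the strain difference. DESeq2 called 373, 702 and 361.

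Of the 132 named and called results, 0 stayed called without each library of its comparison in turn and 0 changed sign. The defence marker genes PR1 and PDF1.2 had 141 and 5 counts in all 12 libraries and were not tested.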

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

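Tests of the ipdc 24 h genes were chosen only after the result was seen, and the fits with covariates or without both ipdc 24 h libraries were added after the data were seen. Tests of the 7 d difference in counts were written before their results were seen.

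The response to Az39 differed between 7 d and 24 h for 8 genes by the test of the difference itself. GSTU5 (AT2G29450), a glutathione S-transferase gene, stood at 4.14 at 7 d and -0.34 at 24 h, a difference of 4.49 (adjusted p = 0.0114), and its relative GSTU6 (AT2G29440) at 3.53 and 0.31, a difference of 3.21. AT3G62010 stood at 2.94 and -0.34, a difference of 3.28. The elicitor peptide precursor gene PROPEP4 (AT5G09980) stood at 2.62 and 0.15, a difference of 2.46, and the methylesterase gene MES5 (AT5G10300) at 2.41 and 0.11, a difference of 2.29. The difference between the strains changed for 2 genes: GSTU5 was 9.82-fold higher with Az39 than with ipdc at 7 d and stood at -1.58 at 24 h, a difference of 4.88 (adjusted p = 0.0054), and AT1G78830 stood at 1.18 and -1.29, a difference of 2.47 (adjusted p = 0.0154).

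The response to ipdc differed between times for 20 genes. The malate transporter gene ALMT1 (AT1G08430) stood at 2.55 at 7 d and -0.60 at 24 h, a difference of 3.16 (adjusted p = 0.0414). The other named genes stood higher at 24 h than at 7 d. The ipdc 24 h libraries held the highest photosynthesis shares of all, 0.398% and 2.32%. Of 27 photosynthesis genes 0 were above 0 in this difference (median -2.65, camera adjusted p = 1.5e-09, p = 0.1825 with an estimated correlation). The cytosolic fructose-1,6-bisphosphatase gene FBP (AT1G43670) was at 0.20 at 7 d and 2.03 at 24 h (difference -1.83), and the chloroplast elongation factor gene SCO1 (AT1G62750) at -0.47 and 1.66 (difference -2.13). AT5G24490 was at -0.48 and 1.76 (difference -2.24, adjusted p = 0.0081), and the circadian gene ELF4 (AT2G40080) at -0.61 at 7 d, with a higher value at 24 h (difference -2.30). Without the second ipdc 24 h replicate 826 genes differed, and without the second saline 24 h replicate 0 did.

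In ipdc against saline at 24 h, 398 genes were called while the ipdc libraries held the highest seed storage and photosynthesis shares of the 12. A trend with the photosynthesis share alone is argued against as the whole cause, since with that share as a covariate 145 of the 398 were still called (438 in all). The median log2 fold change of the 398 in the called direction was 1.49 (median SE 0.394) against 1.77 (median SE 0.324) before. With both shares as covariates 0 genes were called, so the tissue make-up of the ipdc libraries as a whole is not argued against. A trend with the seed storage share cannot be told apart from the treatment: 1 of the 398 was still called (3 in all), but the median was 1.68, all 398 kept their sign, and the call ended as the median SE rose to 0.436. Shoot tissue in the second ipdc replicate is argued against as the whole cause, since 307 of the 398 stayed called without that library, and the median over the 398 was 1.62 (median SE 0.312). For the genes not called without the second ipdc replicate, shoot tissue in it stays open. Its share of shoot transcripts outside photosynthesis was 1.84 times the saline mean, where the photosynthesis share was 17.9 times. A library of another group reached 0.0338% of such shoot transcripts, against 0.0347% in the second ipdc replicate. As a list added after the data were seen, those shoot genes had 10 of 10 above 0, with 1 higher over all genes and 2 adjusted over the list alone (median 1.23, camera adjusted p = 0.0018, p = 0.143 with an estimated correlation). Early touch and wound genes also stood higher, with 14 of 14 above 0 and 0 called (median 1.22, camera adjusted p = 0.0040, p = 0.343 with an estimated correlation), so handling at harvest cannot be told apart either. Without the first ipdc replicate the median over the 398 was 1.84 (median SE 0.304). A response to the ipdc strain is also open.

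At 7 d 696 genes were called for Az39 and 3 for ipdc. A deeper Az39 group is argued against, since 701 genes were called after thinning to the depth of the smallest library of the time, 672 of them among the 696. The same response to both strains, parted by the threshold alone, is argued against by the direct comparison only for 20 of the 696 genes, which were among the 22 called there. Of the 696 genes 57.3% had an unadjusted p under 0.05 there, while 20 simulations of a shared response gave a mean of 13.5% and called 0 to 1 genes. Those simulations called 766 to 954 genes for Az39 and 815 to 955 for ipdc, so they matched the data only in part. They drew each gene on its own, without shifts of many genes together, so for the other genes the question stays open. A weaker response of the same kind to the mutant may be part of the difference, as a hypothesis. For ipdc 98.4% of the 696 genes had the same sign as for Az39, with a median ratio of the log2 fold changes of 0.535. In 20 simulations with the same saline libraries for both strains and no response to ipdc, added after the data were seen, these were 65.6% to 69.5% and a mean of 0.112. Those simulations called 1855 to 2139 genes for Az39, more than the data did, so they matched the data only in part and decide nothing alone. Touch or wounding at harvest of the Az39 roots cannot be told apart, with a median of 0.58 (0.579) over the 14 early touch and wound genes and members going both ways. Against a larger effect in Az39 roots, the list stood higher with ipdc (1.08, 13 of 14 above 0), and at -0.20 with 5 of 14 above 0 between the strains.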

How the results depend on the processing

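The fits without both ipdc 24 h libraries and with covariates were added after the data were seen. Each alternative changed 1 choice, except that both shares entered together and DESeq2 also used its own scaling. For values that moved the cause was not tested, except that fits to fewer libraries and with a library left out had fewer residual degrees of freedom, and a 1.5-fold threshold asks for larger effects. RLE scaling and the removal of organelle genes kept each count of genes within 1.5 times. DESeq2 called 2 genes for Az39 at 24 h, 1399 for ipdc at 24 h, 1981 for Az39 and 379 for ipdc at 7 d, 1394 and 184 between the strains at 24 h and 7 d, and 373, 702 and 361 for the differences between times (Az39, ipdc, Az39 minus ipdc), with 2 and 277 genes shared by both strains. limma-voom called 1085 for Az39 at 7 d and 74 and 35 between the strains. Without a low-count filter 5 were called for ipdc at 7 d and 7 for the strain difference over time.

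A test against a 1.5-fold change gave 14 for ipdc and 8 between the strains at 24 h, 85 for Az39, 0 for ipdc and 3 between the strains at 7 d, 226 for saline over time, and 5 and 1 for the Az39 and ipdc differences between times. Fits to the libraries of the time alone gave 0 for ipdc at both times and 0 between the strains at 24 h, as did fits to the groups compared alone, which gave 69 for Az39 at 7 d. The replicate mark as a block gave 6 for ipdc at 7 d, 1 for the ipdc and 6 for the strain difference over time; within each time it gave 37, 326, 0, 6, 4 and 299 for ipdc at 24 h, Az39 at 7 d, ipdc at 7 d, the strains at 24 h, the strains at 7 d and saline over time, and 0, 0 and 1 for the differences between times. The mark did not pair the libraries: correlations of the replicate deviations between groups ran from -0.234 to 0.272. The seed storage share as a covariate gave 3 for ipdc and 4 between the strains at 24 h and 0 for ipdc at 7 d. The photosynthesis share gave 603 between the strains at 24 h and 0 for ipdc at 7 d. Both shares gave 0 for ipdc and 2 between the strains at 24 h, and 437, 0 and 5 for Az39, ipdc and the strains at 7 d. Without both ipdc 24 h libraries 1199 genes were called for Az39 at 7 d and 18 for the Az39 difference between times. An adjusted p under 0.01 left 0 genes shared at 7 d.

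Leaving out single libraries gave 0 to 0 genes for Az39 at 24 h, 0 to 1318 for ipdc at 24 h, 4 to 638 for Az39 at 7 d, 0 to 8 for ipdc at 7 d, 0 to 1356 and 0 to 6 between the strains at 24 h and 7 d, 27 to 2278 for saline over time, and 0 to 36, 0 to 826 and 0 to 402 for the differences between times. Shared genes at 7 d ranged from 0 to 8, and the covariance from 0.299 to 0.573 at 7 d and from -0.0612 (reversed, without the second Az39 replicate) to 0.616 at 24 h. Of the list tests 53 to 60 passed against 54, while 0 passed with estimated correlations and 1 with fry. For Az39 at 24 h leaving out single libraries reversed the camera direction of some lists. The medians of pattern-triggered immunity ranged from -0.683 to 0.0518, nitrogen from -0.44 to 0.14, suberin from -0.77 to 0.55 (-0.14 without the second Az39 replicate), aquaporins from -0.34 to 0.14 (0.03 without the second Az39 replicate), and photosynthesis from 0.0930 to 1.31. The -0.14 and 0.0930 had the sign of the full data, and only the rank against other genes turned. Cell cycle ranged from -0.03 to 0.37 and kept its camera direction. For the strains at 7 d hypoxia ranged from -0.11 to 0.65.

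Of the 132 named and called results DESeq2 kept the call of 132, RLE 131, the block 110, limma-voom 90 and the block within each time 48. With a library left out, the call was kept 197 times and lost 379 times. Thinning the Az39 7 d libraries to the smallest library of that time gave 701 calls, and depth was varied in no other comparison.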

Other observations

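The gene lists of this part, and the tests of seed transcripts, were chosen only after the data were seen, and nothing here was planned beforehand.

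Genes of methionine-derived (aliphatic) glucosinolate synthesis, defence compounds of the cabbage family, stood higher with Az39 at 24 h: 16 of 18 were above 0, with 0 called over all genes and 7 higher and 1 lower adjusted over the list alone (median 0.72, camera adjusted p = 3.2e-19, p = 0.0269 with an estimated correlation). After adjustment over the added lists this was lost with an estimated correlation (adjusted p = 0.895) and with fry (0.534). The estimated correlation was 0.65, against the preset 0.01. The added lists were not tested with single libraries left out. BCAT4 (AT3G19710), the aminotransferase of the entry step, stood at 1.45 ± 0.40, CYP83A1 (AT4G13770) at 0.89 ± 0.37 and SOT18 (AT1G74090) at 0.80 ± 0.21, none past the threshold over all genes. Against ipdc 1 of 18 was called higher and 1 lower over all genes, or 11 and 2 adjusted over the list alone (median 0.88, camera adjusted p = 6.7e-08, p = 0.11 with an estimated correlation). The called genes were IPMI1 (AT3G58990), at 1.17 ± 0.20, adjusted p = 0.0398, and CYP79F1 (AT1G16410), at -5.81 ± 0.94, adjusted p = 0.0313, while its close relative CYP79F2 (AT1G16400) stood at 1.34 ± 0.30. At 7 d the list had a median of 0.02 with Az39 and -0.28 with ipdc.

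Early touch and wound genes stood higher in saline roots at 7 d than at 24 h. Of 14 tested, 6 rose over all genes and 14 adjusted over the list alone (median 2.61, camera adjusted p = 5.9e-06, p = 0.165 with an estimated correlation), and 4 of the list are also in the fixed immunity or ethylene lists. The calcium sensor gene CML37 (AT5G42380) rose by 3.56 ± 0.94, adjusted p = 0.0327 and the zinc finger gene ZAT10 (AT1G27730) by 3.08 ± 0.87, adjusted p = 0.0402. With ipdc at 7 d the median was 1.08 against saline, with 0 of 14 called (median 1.08, camera adjusted p = 0.0014, p = 0.293 with an estimated correlation). With ipdc at 24 h 14 of 14 were above 0 and 0 were called over all genes (median 1.22, camera adjusted p = 0.0040, p = 0.343 with an estimated correlation). Between Az39 and ipdc at 24 h 0 of 14 were above 0 (median -1.32, camera adjusted p = 0.0043, p = 0.351 with an estimated correlation). Touch or wounding of the ipdc roots at that harvest was not decided.

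Seed storage transcripts filled 5.11% of the first ipdc 24 h replicate. Its log2 ratio of the SESA1 to SESA4 counts to the CRA1 count was -6.19, and the second ipdc 24 h replicate had -5.48. The 9 libraries outside this group with enough CRA1 counts ranged from -4.72 to 0.6, with both times pooled. At 24 h the saline replicates had -0.47 and -1.97 and the second Az39 replicate 0.6. The first Az39 replicate, with 72 CRA1 counts, had -3.27. All 7 d libraries lay between -4.72 and -3.41. These values argue against seed RNA of the same make-up as in the other 24 h libraries. Seed RNA of the make-up in the 7 d libraries stays open. A response to the ipdc strain cannot be told apart either, since the shares of the ipdc 24 h replicates differed 17.3-fold, where saline replicates differed 5.7-fold and 20.2-fold and Az39 24 h replicates 85.1-fold.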
